A study of Rattus norvegicus with 4 samples.

How the data were processed

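Nuclei were isolated from the brainstem of 4 rats by lysis and Dounce homogenization and captured in droplets with the 10x Genomics 3' chemistry (version 3), per the labels' protocols, with loading aimed at 8000 nuclei and at least 20000 reads per nucleus. Each rat gave 1 library: 2 rats with brainstem ischemia and 2 with ischemia and mPES, and the series description states 2 separate animals per group. The deposited values are whole-number UMI counts per gene and barcode, not normalized. Per the file headers the matrices were written by Cell Ranger 8.0.1, which counts unique molecular identifiers, so reads copied by amplification are counted once. The submitters' processing notes also name Seurat 3.1.1 and the genome builds mRatBN7.2, GRCh38 and GRCm38, without saying which role each had; which filters were run before deposit is not given in the sources used here. Of 30562 features, 23434 symbols matched a table of rat genes (assembly GRCr8), which was used for names and for gene neighbours only. Xist, Foxj1, Cldn5 and Gapdh were not used here, and some genes are not reported here. Dense copies of the same counts were not used here.

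The 4 matrices held 40930 barcodes. Nuclei were kept with at least 500 UMIs, at least 300 genes and at most 10% of UMIs from mitochondrially encoded genes, which removed 1 barcode. Doublets were scored with Scrublet (scanpy 1.11.5) in each library at an expected rate of 8%. Its automatic threshold marked 3 nuclei (0.00733%), so it had not worked, and nuclei scoring above the limit of the top 8% in each library were removed instead, with ties at the limit kept: 676, 838, 691 and 823 nuclei in ischemia rats 1 and 2 and mPES rats 1 and 2, all with scores of at least 0.236. This left 37901 nuclei. They were clustered with the Leiden method (leidenalg 0.10.2, resolution 1) on principal components of log-normalized counts, and clusters were named from marker genes fixed before the data were examined; no cell annotation of the authors was used here. How markers were turned into names was adjusted after the clusters were seen and before any test between groups. Of 49 clusters, 20 stayed unnamed, because markers of several classes were mixed or too few were found; they held 20.6%, 22.7%, 22.2% and 23.1% of the nuclei of the 4 rats and entered only the fit over all nuclei. Neurons were clustered again to separate excitatory, inhibitory, cholinergic and monoaminergic neurons. Of the classes, 12 had at least 30 nuclei in every rat and were compared.

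UMI counts were summed over the nuclei of a class in each rat, so that rats and not nuclei are the replicates, and the sums were tested with edgeR 4.0.16 in R 4.3.3 (quasi-likelihood F test, TMM normalization, filterByExpr, Benjamini-Hochberg adjustment within each class, threshold 0.05, mPES against ischemia). Log2 fold changes are edgeR's fitted values, SE is the log2 fold change divided by the square root of F, and values per rat are CPM with TMM scaling, or without it for hemoglobin, genes of the Y chromosome, sums over myelin proteins and OPC-marker nuclei. With 2 rats per group, edgeR's p-values rest on the spread between these 4 animals, estimated with information shared over genes. Camera with a preset correlation sets the members of a list against the other genes. Its p-values therefore do not measure the spread between animals, however small they are. Named genes followed a rule set before the data were examined: genes past the threshold with a mean of at least 10 CPM, both mPES rats on the same side of both ischemia rats and a gene symbol, up to 8 rising and 8 falling per class and 12 and 12 over all nuclei, filled up to 8 by the smallest p where fewer passed, and the 4 members of smallest p in each gene list described. Mki67, Ccnd1 and Mblac1, Stac and genes given for a single rat (Fkbp5, Zbtb16, Pdk4, Errfi1) were added after their values were seen, except where a list names them. Gene lists, 44 in all and also fixed before the data were examined, were tested in each class where at least 5 members passed the filter, 444 tests in all, with camera (limma 3.58.1, correlation preset to 0.01) and one Benjamini-Hochberg adjustment over all of them. With an estimated correlation, or with fry, 0 lists passed, so each list call holds only under the preset correlation. These 2 alternatives draw on the spread between only 4 rats and were not tried on simulated counts. A list that fails in them therefore cannot be read as unchanged. Shares of nuclei were tested with edgeR on the number of nuclei per class, and the difference of response between excitatory and inhibitory neurons as an interaction with the rat as a block.

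Shares of nuclei with cell cycle UMIs were compared after thinning each nucleus to 1000 UMIs, leaving out shallower nuclei. Intervals are exact 95% binomial or Poisson intervals, ratios with 1 to 3 UMIs in a group have an exact interval conditional on the total, and a count of 0 is read against a floor of 3 counts over the group; these cover counting error only. Alternatives chosen before the data were examined were DESeq2 1.42.0, DESeq2's size factors (RLE) in edgeR, no filter on low counts, the replicate number as a block, each rat left out in turn, doublets kept, limma on log2(CPM + 1) with nuclei of equal weight, all deposited barcodes, Leiden resolution 2 and, for shares, at least 1000 UMIs per nucleus or oligodendrocytes left out of the total. With a rat left out, 1 group has a single rat, which is assumed to vary like the other group.

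The tests were tried on simulated counts with the real means and library sizes and 100 genes changed 2-fold and 100 changed 4-fold. All changed genes were drawn from those above a minimum mean count, so genes of low count were not tried. For the OPC comparison 59% of the 2-fold and 100% of the 4-fold changes were called, for all nuclei 65% and 93%, for neurons 67% and 98%, for oligodendrocytes 51% and 99%, for astrocytes 62% and 100%, for microglia 24% and 96% and for endothelial cells 21% and 96%. Unchanged genes called by edgeR numbered from 2 in excitatory neurons to 14 in OPCs, the most of any fit. Camera called 5 of 5 changed lists and 0 of 35 unchanged ones, and the interaction test found 187 of 200 genes changed 4-fold. The changed lists mixed unchanged genes with genes raised 2-fold or 4-fold, so lists whose members each move by less were not tried. Simulated genes were drawn independently of each other. The simulation therefore cannot show how often camera calls an unchanged list whose members move together. Simulated genes were given the fitted trend of the spread, and Nr4a1 and Egr1 in endothelial cells lay under the minimum mean count. Differences of over 4-fold in the data did not always pass (Nr4a1 and Egr1 in endothelial cells, Pilrb-ps6 over all nuclei). These shares therefore do not carry over to each gene, least of all to genes of low count. Other tools were python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.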

Results

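RNA was measured in single nuclei from the brainstem of 4 Sprague-Dawley rats. In 2 rats the brainstem had been made ischemic, a model of the swallowing disorder (dysphagia) that follows brainstem stroke. The other 2 rats had the same ischemia and also received modified pharyngeal electrical stimulation (mPES), a stimulation of the throat that is used against dysphagia. The comparison asks what mPES changes in brainstem cells after ischemia. Rats without ischemia were not analysed here, so every difference below is one between stimulated and unstimulated ischemic rats, with n = 2 rats per group. The deposited matrices held 9685 and 11359 nuclei of ischemia rats 1 and 2 and 9293 and 10593 nuclei of mPES rats 1 and 2. They summed to 48363807, 54313500, 45482741 and 42506693 unique molecular identifiers (UMIs), each of which stands for 1 captured RNA molecule. The median nucleus of the ischemia rats held 3669 and 3598 UMIs and that of the mPES rats 3797 and 2811 UMIs. After filtering, 37901 nuclei remained.

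Genes of the Y chromosome were present at like levels in the 4 rats. Values per gene are given as UMI counts scaled to a common library total (CPM). Uty had 194 and 179 CPM in the ischemia rats and 201 and 171 in the mPES rats, and Kdm5d had 64.3, 63.8, 65.0 and 56.2. Usp9y was near 0 in 3 rats (0.117, 0.207 and 0.212 CPM) and stood at 2.50 in mPES rat 1, and Ddx3y was near 0 in each. Hemoglobin transcripts, which come from red blood cells, were at 8.77, 7.84 and 14.1 CPM for Hbb in ischemia rats 1 and 2 and mPES rat 1, and at 75.5 in mPES rat 2. In neurons Hbb was at 4.19 and 5.26 against 9.67 and 14.6 CPM (edgeR adjusted p = 0.754, DESeq2 0.0224), and in OPCs Hba-a1 at 4.93 and 3.64 against 27.9 and 36.9, from 2, 2, 8 and 19 UMIs (edgeR adjusted p = 0.0345, among the genes that rose there). The share of UMIs from mitochondrially encoded genes was also highest in mPES rat 2, with a median of 0.137% per nucleus against 0.0498%, 0.0403% and 0.0434%. Rats of 1 group differed by more than sampling noise, with a mean chi-square per gene of 33.3 between the ischemia rats and 40.5 between the mPES rats.

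Neurons, oligodendrocytes and astrocytes made up most named nuclei in each rat, and no class passed the test of its share. Oligodendrocytes, the myelin-forming cells, were 21.6% and 17.9% of nuclei in the ischemia rats and 16.5% and 31.6% in the mPES rats (19.8 ± 2.62 against 24.0 ± 10.7, SD, n = 2 each). Cholinergic neurons, which include the motor neurons of the brainstem, were 0.411% and 0.770% against 1.16% and 1.00%, a log2 fold change of 0.87 with a standard error (SE) of 0.48. Microglia, the resident immune cells of the brain, were 2.57% and 2.45% against 1.80% and 1.27%, a log2 fold change of -0.71 with an SE of 0.41. Among nuclei with at least 1000 UMIs the log2 fold change of microglia was -1.40 (SE 0.49, adjusted p = 0.214). The edgeR test over 16 classes gave an adjusted p of 0.752 for both classes over all depths, and the exact permutation test of 2 against 2 rats cannot go below 0.33. Choroid plexus epithelium, which makes cerebrospinal fluid, was 0.799% of nuclei in ischemia rat 1 and 0.0665%, 0.0465% and 0.0409% in the other 3 rats (edgeR adjusted p = 0.698). Without ischemia rat 2 its adjusted p in edgeR was 0.00376. Between 20.6% and 23.1% of the nuclei of a rat lay in clusters left unnamed, and a share also depends on dissection and on the yield of nuclei.

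**Figure D1:**
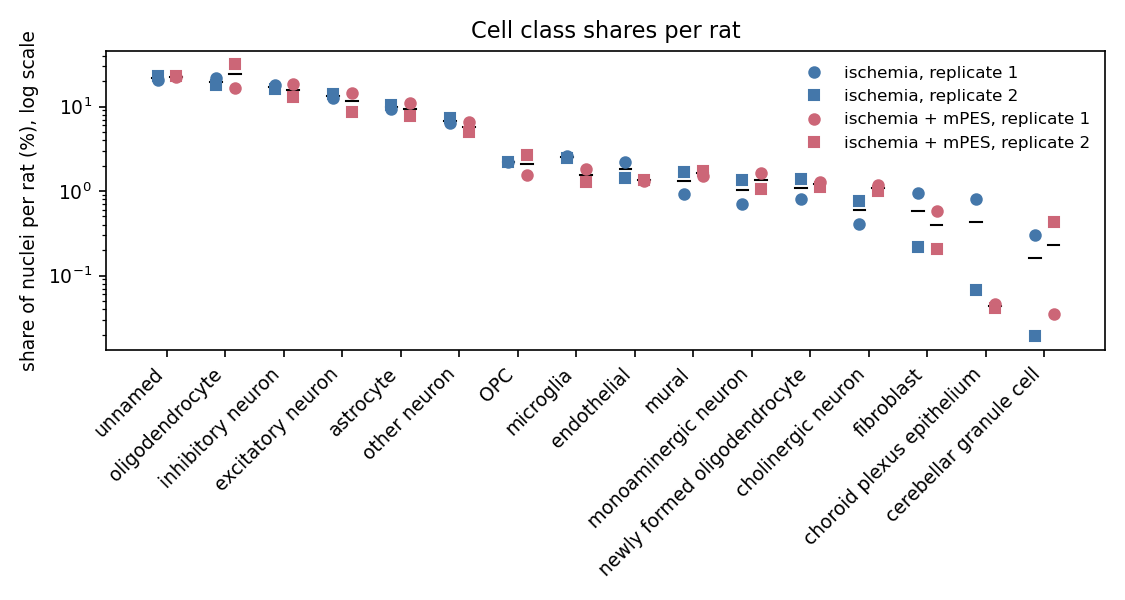
Share of nuclei in each cell class (percent of the nuclei used, logarithmic axis) for each of the 4 rats, blue for ischemia and red for ischemia with mPES, with circles for replicate 1 and squares for replicate 2. Microglia lay at 2.57% and 2.45% in the ischemia rats and at 1.80% and 1.27% in the mPES rats, and no class passed the test.

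The clearest difference was in oligodendrocyte precursor cells (OPCs), the dividing progenitors of oligodendrocytes: mitotic genes rose in the mPES rats. Top2a, the topoisomerase that untangles DNA before cell division, was at 0 and 7.84 CPM in OPCs of the ischemia rats and at 292 and 153 in those of the mPES rats (log2 fold change 5.48, SE 0.55, edgeR adjusted p = 0.000214). Cenpe, a kinetochore motor, rose from 10.6 and 5.88 to 79.4 and 60.4 CPM (log2 fold change 3.06, SE 0.47, adjusted p = 0.00349), and the proliferation marker Mki67 from 5.29 and 9.81 to 57.7 and 50.4 (2.72, SE 0.49, adjusted p = 0.0115). Other spindle and kinetochore genes had 1 or 2 UMIs in all OPCs of the ischemia rats, so only a ratio with its counting interval is given. The ratio was 50.6 for the kinetochore gene Cenpf (exact 95% interval 13.6 to 425), 66.7 for the spindle motor Kif11 (11.5 to 2681), 67.9 for Tacc3 (11.7 to 2728) and 50.0 for the spindle assembly factor Tpx2 (8.5 to 2022). Troap, Ckap2 and Kif14 had no UMI in OPCs of the ischemia rats and were at least 17.9-fold, 9.93-fold and 9.53-fold higher in the mPES rats, against a floor of 3 counts over the group.

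Over all 7392 genes tested in OPCs, 82 rose and 5 fell. Of the cell cycle list, fixed before the data were examined like the other lists, 6 of 23 members could be tested and 5 rose, adjusted over all genes and adjusted over the list alone. Ccnd1 was the exception with a log2 fold change of 0.12. The list as a whole was higher (camera, adjusted p = 2.29e-33, and 0.945 with an estimated correlation). The filter on low counts keeps a gene that is high enough in 1 group alone. Top2a, with 0 and 4 UMIs in OPCs of the ischemia rats and 81 and 76 in the mPES rats, entered in this way. The number of members that rose and the list's p therefore depend in part on the filter and are not separate support. The 5 genes that fell were Thsd7b (log2 fold change -1.93, SE 0.37), Tusc3 (-1.22, SE 0.26), the guanine nucleotide exchange factor Arhgef3 (-1.02, SE 0.22), the heparan sulfate proteoglycan Gpc5 (-0.98, SE 0.17, adjusted p = 0.00774) and the potassium channel gene Kcnh7 (-0.69, SE 0.16). Leaving out mPES rat 2 ended the call of each of them (adjusted p from 0.226 for Thsd7b to 0.340 for Arhgef3). Leaving out mPES rat 1 ended those of Tusc3, Arhgef3 and Kcnh7 (0.0768, 0.0768 and 0.389), and leaving out ischemia rat 1 those of Tusc3 and Arhgef3 (0.0575 and 0.209). Tpx2 had an adjusted p of 0.0597 without mPES rat 2, Ckap2 of 0.0638 without ischemia rat 2 and 0.103 without mPES rat 1, and Kif14 of 0.0789 without ischemia rat 2. Myelin protein genes were also higher in OPCs, with 15 of 19 members positive (camera, adjusted p = 6.13e-08; adjusted p = 0.945 with an estimated correlation). Mbp (log2 fold change 0.81, SE 0.17), Mog (1.03, SE 0.23) and Cldn11 (1.16, SE 0.27) rose adjusted over all genes, and 8 members rose adjusted over the list alone. DESeq2 called 21 genes in OPCs and limma on equally weighted nuclei 14, and the count was 205 without ischemia rat 2 and 39 without mPES rat 2. With doublets kept, or without the smaller of the 2 OPC clusters, 1 gene passed, Gpc5. Over nuclei with at least 5 OPC marker UMIs per 1000, whatever their cluster and doublet score, 5 of 9690 genes passed (a fit added after the data were seen): Top2a (5.02, SE 0.45, adjusted p = 0.00253), Cenpf (4.54, SE 0.51), Ndc80 and Cenpp were higher and Ctss was lower. In these nuclei Cenpe was at 9.44 and 3.66 against 23.1 and 27.2 CPM and Mki67 at 5.90 and 6.59 against 14.9 and 21.1, smaller differences than in the class. Kif11, Tacc3 and Tpx2 had log2 fold changes of 3.5, 3.2 and 3.6 there, smaller than the 5.7, 5.7 and 5.3 in the class. They had 2 and 2, 3 and 3, and 1 and 2 UMIs in such nuclei of the ischemia rats. The edgeR adjusted p was 0.059 for Kif11, Tacc3 and Troap and 0.0744 for Tpx2. Among the genes that fell in the class it went from 0.156 for Arhgef3 to 0.918 for Gpc5. Ndc80, Cenpp and Ctss were chosen after their values were seen. Ctss is a microglial gene, and the OPC-marker nuclei came from any cluster with doublets kept, so its fall cannot be placed in OPCs.

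The mitotic transcripts sat in a minority of OPC nuclei. With each nucleus thinned to 1000 UMIs, at least 2 cell cycle UMIs were found in 4 of 193 OPC nuclei of ischemia rat 1 (2.07%, exact 95% interval 0.568 to 5.22%) and 5 of 227 of ischemia rat 2 (2.20%, 0.719 to 5.07%), against 27 of 133 in mPES rat 1 (20.3%, 13.8 to 28.1%) and 23 of 245 in mPES rat 2 (9.39%, 6.04 to 13.8%). Thinning left out 3, 3, 0 and 13 nuclei with fewer UMIs, and the shares without thinning were 4.59%, 13%, 34.6% and 19.8%. Neurons, which do not divide, gave 0.0880%, 0.289%, 0.0824% and 0.107% after thinning and 4.99%, 4.12%, 3.24% and 3.5% without it. The median OPC nucleus held 2034, 2268, 1961 and 1795 UMIs and the median neuron 5868, 4962, 5040 and 5177. The smaller OPC cluster, led by Top2a and Diaph3, held 0, 4, 38 and 33 nuclei and the larger one 196, 226, 95 and 225. These sizes were not tested, because the genes that define the smaller cluster are those that differ. Among nuclei of any cluster with at least 5 OPC marker UMIs, the share with at least 2 cell cycle UMIs was 1.21%, 0.809%, 5.65% and 4.88% after thinning and 7.43%, 7.07%, 8.10% and 9.08% without it. Nuclei with at least 4 cell cycle and 10 OPC marker UMIs numbered 13, 12, 29 and 33 over all clusters, of which 0, 3, 18 and 17 lay in the OPC class and 11, 8, 7 and 10 in unnamed clusters. OPCs as a class were 2.18% and 2.19% of nuclei in the ischemia rats and 1.55% and 2.64% in the mPES rats.

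**Figure D2:**
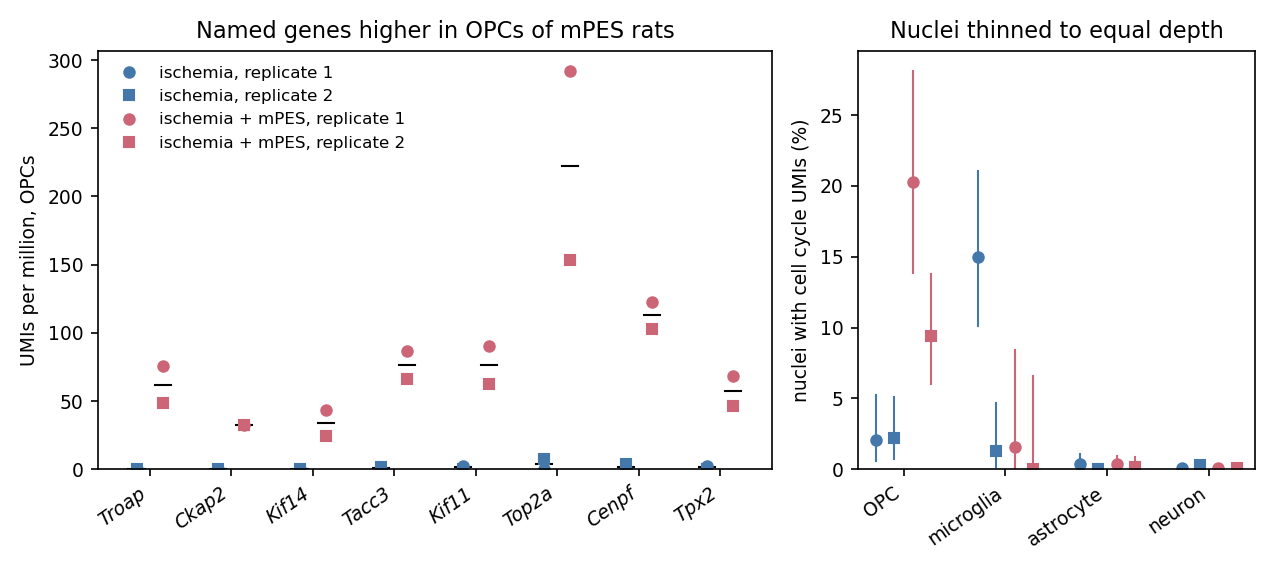
Left, CPM of 8 mitotic genes in OPCs of each rat, with the group mean as a black line; right, percent of nuclei with at least 2 cell cycle UMIs after thinning to 1000 UMIs, with exact 95% binomial intervals, in OPCs, microglia, astrocytes and neurons. In OPCs both mPES rats (20.3% and 9.39%) lay above both ischemia rats (2.07% and 2.20%), and in microglia ischemia rat 1 stood apart at 15.0%.

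In the other 11 classes and over all nuclei, few single genes stood out against 2 rats per group. In microglia 1 of 5443 genes changed: Pilrb-ps6, of the paired immunoglobulin-like receptor family, was at 481 and 630 CPM in the ischemia rats and at 31.3 and 0 in the mPES rats (log2 fold change -5.00, SE 0.56, adjusted p = 0.00409). Its count is uncertain, since neither reads shared with other members of its family nor a sequence difference between the rats at this locus was tested. Over all nuclei it was at 7.88 and 7.46 against 0.378 and 0.0262 CPM. Chat, the acetylcholine-synthesizing enzyme of motor neurons, was at 10.2 and 11.5 CPM in neurons of the ischemia rats and at 19.9 and 20.0 in those of the mPES rats (log2 fold change 0.88, SE 0.13), and Col16a1 at 42.9 and 42.0 against 66.7 and 75.0 (0.74, SE 0.10). Neither passed in edgeR (adjusted p = 0.754), and both did in DESeq2 (adjusted p = 0.0224 and 0.000249). Within cholinergic neurons Chat was at 277 and 223 against 248 and 283 CPM (0.09, SE 0.20), and the share of cholinergic neurons, 0.411% and 0.770% against 1.16% and 1.00% of nuclei, moved with its level over neurons. In monoaminergic neurons the noradrenaline transporter Slc6a2 was at 4.32 and 5.37 against 29.9 and 37.7 CPM (2.69, SE 0.48, adjusted p = 0.9998). The sub-cluster with Slc6a2 and Th among its leading genes held only 17 and 5 nuclei of the ischemia rats and 10 and 7 of the mPES rats. Th, added after its values were seen, went the other way, at 127.5 and 7.52 against 21.0 and 14.7 CPM (-1.65, SE 0.96). In oligodendrocytes Kcnip1, a potassium channel subunit, was at 329 and 237 against 97.9 and 112 (-1.43, SE 0.19, adjusted p = 0.933; DESeq2 3.62e-05). In mural cells, which wrap small vessels, Col18a1 was at 279 and 194 against 549 and 799 (1.58, SE 0.32, adjusted p = 0.214). With the replicate number as a block, which was not shown to pair the rats, its edgeR adjusted p was 0.00172. Astrocytes had Hmgcs1, an enzyme of cholesterol synthesis, at 91.5 and 104 against 164 and 205 (0.91, SE 0.17, adjusted p = 0.743). Over all nuclei the microglial genes Ctss (49.6 and 48.7 against 20.6 and 28.8; -0.99, SE 0.17), Ly86 (-0.77, SE 0.12) and Csf1r (-0.71, SE 0.13) were lower and Plekhb1 higher (0.83, SE 0.14), each at an edgeR adjusted p of 0.912; DESeq2 called Ctss (adjusted p = 0.00272) and Plekhb1 (0.0067).

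The edgeR test called 0 of 17680 genes over all nuclei (813 at an unadjusted p under 0.05), 0 of 16150 in neurons (1025), 0 of 13910 in excitatory neurons (423), 0 of 14263 in inhibitory neurons (1047), 0 of 8856 in cholinergic neurons (371) and 0 of 8594 in monoaminergic neurons (340). It also called 0 of 12579 genes in oligodendrocytes (522), 0 of 5451 in newly formed oligodendrocytes (299), 0 of 11294 in astrocytes (522), 0 of 5998 in endothelial cells (297) and 0 of 3705 in mural cells (166). Outside OPCs, DESeq2 called 15 genes over all nuclei, 22 in neurons, 15 in inhibitory neurons, 2 in astrocytes (Sema3e and a feature with no symbol), 3 in oligodendrocytes (Kcnip1 and 2 features with no symbol), 1 in microglia (Pilrb-ps6) and 0 in the other classes. The limma fit called 14 in OPCs, 1 in microglia and 0 in the other fits. These counts depended on single rats. Without ischemia rat 2 the edgeR count was 11 over all nuclei, 147 in neurons, 145 in inhibitory, 263 in cholinergic and 287 in monoaminergic neurons, 299 in oligodendrocytes, 123 in newly formed oligodendrocytes, 382 in astrocytes, 195 in microglia, 136 in endothelial and 28 in mural cells. Without ischemia rat 1 it was 5, 31, 15, 1, 44, 19, 22, 70, 5, 33 and 3 in the same order. Without mPES rat 1 it was 13 in newly formed oligodendrocytes, 9 in mural cells, 2 in microglia and 1 in endothelial cells, and without mPES rat 2 it was 13 in newly formed oligodendrocytes, 6 in microglia, 3 in mural cells and 3 in neurons. Excitatory neurons had 0 in each case. Grouping the rats by replicate number in place of treatment called 17 genes in excitatory neurons and 16 in astrocytes, and 2 inhibitory sub-clusters held nuclei of rats numbered 1 alone (86 and 81, and 90 and 63).

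Of 444 tests of a gene list in a class, 82 passed under the preset correlation (57 higher and 25 lower in the mPES rats), and 43 did without mPES rat 2. Cholesterol synthesis genes moved together in glia. In oligodendrocytes all 22 members were higher in the mPES rats, with a median log2 fold change of 0.53 (camera, adjusted p = 6.02e-21; adjusted p = 0.945 with an estimated correlation). Examples were Tm7sf2 (1.04, SE 0.27), Lss, which makes lanosterol (1.03, SE 0.30), Cyp51 (0.71, SE 0.22) and Fdps (0.68, SE 0.19); 0 members passed edgeR adjusted over all genes and 0 adjusted over the list alone. Astrocytes had 21 of 22 members higher, with a median of 0.54 (adjusted p = 9.89e-17; 0.945 with an estimated correlation), 0 adjusted over all genes and 4 adjusted over the list alone: Hmgcs1 (0.91, SE 0.17), Fdft1 (0.82), Lss (0.80) and Cyp51 (0.78). Over all nuclei 22 of 22 were higher, with a median of 0.41 (adjusted p = 6.58e-19; 0.945 with an estimated correlation), and 0 passed either adjustment. In OPCs 13 of 15 were higher (median 0.62, adjusted p = 0.000103; 0.945 with an estimated correlation), 0 adjusted over all genes and 3 adjusted over the list alone, and in microglia 11 of 12 (median 0.77, adjusted p = 3.11e-05; 0.945 with an estimated correlation). The calls in oligodendrocytes, astrocytes and all nuclei held with each rat left out. Without ischemia rat 1 the adjusted p was 0.110 in OPCs and 0.215 in microglia, and without mPES rat 2 it was 0.126 in OPCs. Transcripts of myelin proteins moved with the cholesterol genes, summing to 2531 and 2744 against 3305 and 4201 CPM in astrocytes, 2887 and 2819 against 3879 and 4588 in OPCs and 5318 and 4501 against 5649 and 7025 in microglia. A cluster led by Prex2 and Pdk4 held 91.9% of the oligodendrocytes of ischemia rat 1 (1790 nuclei) and 4, 7 and 10 nuclei of ischemia rat 2 and the mPES rats, in which a cluster led by Rnf220 and Rasgrp3 was the largest (64.2%, 75.8% and 65.3%).

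Genes induced by glucocorticoids were lower in oligodendrocytes of the mPES rats, and the difference came from ischemia rat 1. All 16 members measured there were lower, with a median log2 fold change of -0.75 (camera, adjusted p = 9.06e-06; adjusted p = 0.945 with an estimated correlation), and 0 passed either adjustment. Fkbp5, a chaperone induced by the glucocorticoid receptor, was at 335 CPM in oligodendrocytes of ischemia rat 1 and at 39.8, 42.0 and 38.9 in the other 3 rats, and Zbtb16 was at 626 against 45.5, 62.9 and 44.9. Pdk4, a regulator of glucose oxidation, was at 347 against 25.5, 27.2 and 39.6, and Errfi1 at 168 against 116, 72.7 and 110. Fkbp5 was also at 236 CPM in astrocytes of ischemia rat 1 and at 4.00, 8.04 and 6.09 in the others, and at 521 in its microglia against 70.4, 86.1 and 54.1. The list was lower in astrocytes (adjusted p = 0.000705), all nuclei (0.000708), excitatory neurons (0.00151) and microglia (0.0305), with an adjusted p of 0.945 for each with an estimated correlation. Without ischemia rat 1 the adjusted p was 0.142 in oligodendrocytes, 0.623 in astrocytes and 0.137 over all nuclei, now with a positive direction, and 0.242 in excitatory neurons and 0.158 in microglia. Without mPES rat 1 it was 0.149 over all nuclei, 0.171 in excitatory neurons and 0.253 in microglia, and without mPES rat 2 it was 0.140 in microglia.

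**Figure D3:**
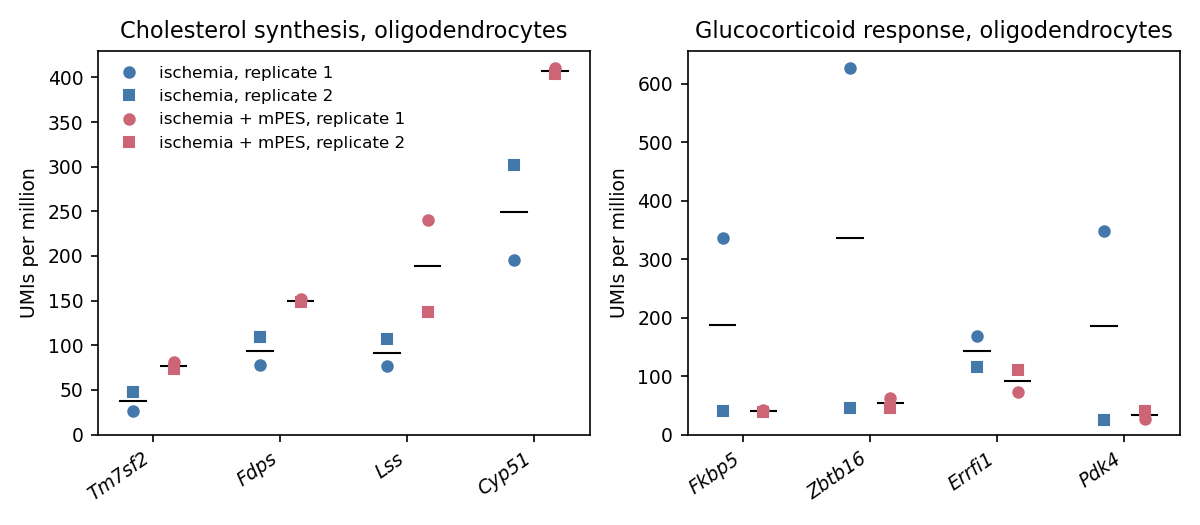
CPM in oligodendrocytes of each rat for 4 cholesterol synthesis genes (Tm7sf2, Fdps, Lss, Cyp51) and 4 glucocorticoid response genes (Fkbp5, Zbtb16, Errfi1, Pdk4), blue for ischemia, red for ischemia with mPES, with the group mean as a black line. For Fkbp5, ischemia rat 1 stood at 335 and the other 3 rats between 38.9 and 42.0.

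Transcripts of myelin proteins were higher in several classes that do not form myelin. In neurons 19 of 20 members were higher in the mPES rats, with a median log2 fold change of 0.57 (camera, adjusted p = 4.99e-20; adjusted p = 0.945 with an estimated correlation). None passed edgeR adjusted over all genes (0), and 14 were higher and 1 lower adjusted over the list alone. Examples were Mag (0.58, SE 0.10), the gap junction gene Gjb1 (1.15, SE 0.25) and Ugt8, which makes myelin galactolipids (0.61, SE 0.14). The list was also higher in excitatory neurons (adjusted p = 1.31e-21), inhibitory neurons (2.4e-17), astrocytes (9.01e-17, 19 of 19 members) and all nuclei (4.96e-10), with an adjusted p of 0.945 for each with an estimated correlation, and these calls held with each rat left out. In oligodendrocytes themselves the list did not pass (median 0.13, adjusted p = 0.0702). It was called in cholinergic neurons (5.9e-06), microglia (8.64e-05), mural cells (0.000828) and monoaminergic neurons (0.00139), each at 0.945 with an estimated correlation. Of these, the adjusted p was 0.488 in cholinergic and 0.306 in monoaminergic neurons without ischemia rat 1, 0.0648 in microglia and 0.156 in mural cells without ischemia rat 2, 0.0751 in monoaminergic neurons without mPES rat 1, and 0.166 in microglia and 0.457 in mural cells without mPES rat 2.

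Mitochondrially encoded genes were higher in 10 of the 13 fits, and mPES rat 2 carried most of it. In astrocytes 13 of 13 members were higher, with a median log2 fold change of 0.88 (camera, adjusted p = 2.31e-19; adjusted p = 0.945 with an estimated correlation), 0 adjusted over all genes and 8 adjusted over the list alone. Examples were Mt-atp6 (1.02, SE 0.21) and Mt-co3 (0.99, SE 0.21). The astrocyte call held without mPES rat 2 (adjusted p = 2.95e-06) and the other 9 did not, with adjusted p from 0.109 in microglia to 0.963 over all nuclei. Without ischemia rat 2 the adjusted p was 0.0617 over all nuclei, 0.289 in oligodendrocytes, 0.528 in monoaminergic neurons and 0.383 in newly formed oligodendrocytes. Ribosomal protein genes were higher over all nuclei (45 of 45 members, median 0.26, adjusted p = 6.9e-07; 0.945 with an estimated correlation) and in astrocytes (39 of 44, median 0.40, adjusted p = 6.73e-10; 0.945 with an estimated correlation), and without mPES rat 2 the adjusted p was 0.515 and 0.329. They were also higher in oligodendrocytes (8.64e-05), excitatory neurons (0.000119), OPCs (0.0087) and, at 0.952 with an estimated correlation, neurons (0.00834) and inhibitory neurons (0.0277); the first 3 had 0.945. Without mPES rat 2 these 5 had adjusted p of 0.388 to 0.921, and without ischemia rat 2 they were 0.213 in oligodendrocytes, 0.0842 in neurons, 0.306 in OPCs and 0.184 in inhibitory neurons. The mitochondrial share of 0.137% in mPES rat 2 moved with both groups of genes.

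Immune and positional genes were lower over all nuclei of the mPES rats. Of the complement genes, which tag cells and debris for removal, 15 of 16 were lower, with a median log2 fold change of -0.56 (camera, adjusted p = 2.32e-05; adjusted p = 0.945 with an estimated correlation); C1qa was at 28.5 and 9.02 CPM in the ischemia rats and at 6.30 and 5.85 in the mPES rats. Of the genes of inflammation and NF-kB signalling 17 of 21 were lower (adjusted p = 0.000187; 0.945 with an estimated correlation), among them the inflammasome gene Nlrp3 (-0.92, SE 0.22) and Nfkbiz (-0.79, SE 0.20). The cytokine Il1b had a log2 fold change of 1.82 (SE 0.48). Homeostatic microglia genes were lower in 13 of 15 cases (adjusted p = 0.0253; 0.945 with an estimated correlation), 0 adjusted over all genes and 1, Csf1r, adjusted over the list alone. The lower share of microglia, which did not pass its test, moved with these 3 groups, and the cluster with 96.1% of the microglia of ischemia rat 1 had the macrophage gene Mrc1 at 492 CPM against 1.84 in the other microglia cluster. The HOX genes of the hindbrain, which mark position along its axis, were lower over all nuclei (11 of 11, adjusted p = 6.96e-05), in neurons (9 of 9, 0.000119), excitatory neurons (8 of 8, 1.91e-05), inhibitory neurons (0.0087) and astrocytes (0.0354), each at 0.945 with an estimated correlation. Hoxc4 was at 16.6 CPM in neurons of ischemia rat 1 and at 3.44, 3.02 and 1.86 in the other 3 rats. Without ischemia rat 1 the adjusted p was 0.415 for complement, 0.0712 for inflammation, and 0.889, 0.906, 0.118, 0.470 and 0.949 for the HOX genes in the order above. Without mPES rat 2 the HOX values were 0.441, 0.163, 0.0699, 0.729 and 0.542. Without mPES rat 1 inflammation had 0.128, and homeostatic microglia had 0.816, 0.0592 and 0.202 without ischemia rat 2, mPES rat 1 and mPES rat 2.

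Immediate early genes, the first genes transcribed when a cell is activated, were higher in endothelial cells of the mPES rats. Of 10 members measured 9 were higher, with a median log2 fold change of 1.00 (camera, adjusted p = 1.53e-14; adjusted p = 0.945 with an estimated correlation), and the call held with each rat left out (adjusted p up to 0.00118 without ischemia rat 2). None passed edgeR adjusted over all genes (0), and 4 were higher adjusted over the list alone. The orphan nuclear receptor Nr4a1 was at 14.7 and 7.79 CPM in the ischemia rats and at 154 and 113 in the mPES rats (3.44, SE 0.49, adjusted p = 0.000373 over the list alone and 0.224 over all genes), and the transcription factor Egr1 at 17.7 and 3.90 against 116 and 84.5 (3.03, SE 0.58, 0.00194 over the list alone). Btg2 had a log2 fold change of 1.69 (SE 0.41) and Jun of 1.43 (SE 0.43). These values rest on few molecules: Nr4a1 had 5, 2, 24 and 24 UMIs in 198, 148, 113 and 133 endothelial nuclei. At Leiden resolution 2 the endothelial class held 376 nuclei against 592 here. A cluster of 225 nuclei led by endothelial genes then stayed unnamed, with a median doublet score of 0.137 against 0.0235 in the class that kept its name. No gene list in endothelial cells, TGF-beta signalling included, was tested on that smaller class. Hemoglobin transcripts moved with the list in this class, with Hbb at 74.9 and 34.4 against 505 and 114 CPM and Hba-a1 at 46.5 and 17.2 against 314 and 59.3 (edgeR adjusted p = 0.933 for both). With the replicate number as a block, which was not shown to pair the rats, edgeR called Hbb and Nr4a1 (adjusted p = 0.0190 for both). It also called Hba-a1 and Btg2 (0.0365 for both). In neurons the list was lower, with 14 of 19 members negative and a median of -0.42 (adjusted p = 0.00546; 0.945 with an estimated correlation). Of these genes Npas4 (-1.38, SE 0.30) and Jund (-1.04, SE 0.25) were lower and Nr4a3 (0.82) higher adjusted over the list alone, and 0 passed over all genes. It was also lower in excitatory neurons (adjusted p = 1.05e-05), astrocytes (0.00525) and inhibitory neurons (0.00972), each at 0.945 with an estimated correlation. The adjusted p was 0.518 in neurons and 0.752 in inhibitory neurons without mPES rat 1, 0.215 in inhibitory neurons without ischemia rat 2 and 0.200 in excitatory neurons without mPES rat 2. In astrocytes it was 0.0773, 0.122, 0.0701 and 0.0972 without ischemia rats 1 and 2 and mPES rats 1 and 2.

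**Figure D4:**
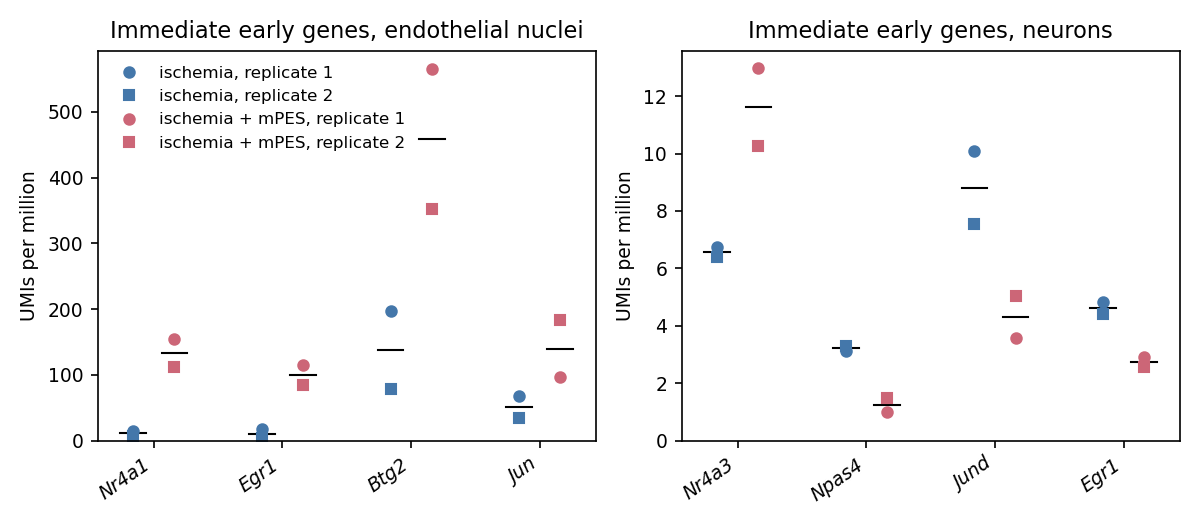
CPM of 4 immediate early genes in endothelial cells (Nr4a1, Egr1, Btg2, Jun) and of 4 in neurons (Nr4a3, Npas4, Jund, Egr1) for each rat, blue for ischemia, red for ischemia with mPES, with the group mean as a black line. In endothelial cells Nr4a1 lay at 154 and 113 in the mPES rats against 14.7 and 7.79 in the ischemia rats.

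Inhibitory neurons of the mPES rats had lower levels of transmitter and receptor genes of the monoamine and neuropeptide systems. Of 32 members 25 were lower, with a median log2 fold change of -0.22 (camera, adjusted p = 0.000149; adjusted p = 0.945 with an estimated correlation). Examples were the serotonin receptor Htr1a (-2.21), the neurokinin receptor Tacr3 (-1.50), the receptor Trhr (-0.82) and the neuropeptide somatostatin (Sst, -0.78), and 0 passed either adjustment. Tacr3 was among the leading genes of an inhibitory sub-cluster with 255 nuclei of ischemia rat 1. The same sub-cluster held 7, 13 and 12 nuclei of ischemia rat 2 and mPES rats 1 and 2. The fall of Tacr3 cannot be told apart from this difference in the make-up of the class. Genes of GABA and glycine receptors were lower in 15 of 20 cases (adjusted p = 0.0488; 0.945 with an estimated correlation), with Gabra2 (-0.49, SE 0.09) lower adjusted over the list alone. Without mPES rat 2 the adjusted p was 0.159 for the first list and 0.445 for the second, and without ischemia rat 1 it was 0.169 for the second. The largest inhibitory sub-cluster was one led by Fign and Cdh8 in the ischemia rats (10.6% of inhibitory neurons, with 2 nuclei of ischemia rat 1 and 347 of ischemia rat 2) and one led by Pax2 and Glra3 in the mPES rats (11.1%).

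Whether excitatory and inhibitory neurons responded differently was tested directly, as the interaction of class and group with each rat as a block. The edgeR test called 0 of 14626 genes (409 at an unadjusted p under 0.05) and DESeq2 0. Among the named genes, Mctp2 had a difference of log2 fold changes of -0.80 between excitatory and inhibitory neurons and the potassium channel gene Kcnh8 one of 0.96. Without mPES rat 1 the count was 1 (Stac), a gene chosen after its value was seen. The excitatory sub-cluster led by Foxp2 and Stac held 205 and 156 nuclei of the ischemia rats, 441 of mPES rat 1 (35.3% of its excitatory neurons) and 2 of mPES rat 2 (0.237%).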

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

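The test of the response of endothelial cells against that of neurons and the test of induction during handling were chosen only after the result was seen. Immediate early genes were higher in endothelial cells and lower in neurons of the mPES rats, and the difference between the classes was tested directly. Over the 9 members that passed the filter on low counts in both classes the median difference of log2 fold changes was 1.25, with 7 of 9 positive (camera, p = 3.19e-13, p = 0.0792 with an estimated correlation and p = 0.0961 with fry). Over all 20 members in the fit of 15347 genes the median was 1.15, with 15 of 20 positive. There camera gave p = 3.87e-05, p = 0.143 with an estimated correlation, and fry gave p = 0.105. Nr4a1 differed by 3.115 (SE 0.75, edgeR adjusted p = 0.0206), Egr1 by 3.817 (SE 0.86, adjusted p = 0.00727) and the antiproliferative gene Btg2 by 2.102 (SE 0.36, adjusted p = 2.18e-05), among 30 of 15347 genes that passed. Over the 9 members the median was 2.45, 0.85, 0.97 and 1.41 without ischemia rats 1 and 2 and mPES rats 1 and 2.

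Induction of these genes while the tissue was handled cannot be told apart from an effect of the stimulation: their median log2 fold change in neurons was -0.4151, but the neuron values are part of the pattern, and the list in neurons had an adjusted p of 0.518 without mPES rat 1. That a few endothelial nuclei carry the signal is argued against by the 2 nuclei with the most UMIs of the list, which held 8.63% and 10.14% of them in the mPES rats (7.61% and 12.3% in the ischemia rats). RNA of another compared class in the endothelial droplets is argued against as well, since Nr4a1 and Egr1 together stood at 206 CPM in endothelial cells of the mPES rats (95% Poisson interval 164 to 255) and at 48.73 in mural cells, the next highest class (26.0 to 83.3). Blood cells were not among the compared classes and hemoglobin moved with the list in endothelial cells, so RNA of blood cells stays open. The unnamed clusters were not compared either. In 1 of them, with 684 nuclei, Hbb, Hba-a1, Tagln and Myh11 were among the leading genes and mural and oligodendrocyte markers were mixed. RNA from the cells of such clusters stays open as well. An effect of the stimulation on vessels is a further hypothesis, and differences between the rats in anaesthesia or in the time from stimulation to tissue collection were not tested.

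Hemoglobin transcripts, which belong to none of the compared classes, stood out in mPES rat 2 over all nuclei, with 75.54 CPM for Hbb and 42.17 for Hba-a1 against at most 14.1 and 11.4 in the other 3 rats. In endothelial cells mPES rat 1 stood out instead, with 505 CPM for Hbb and 314 for Hba-a1 against 114 and 59.3 in mPES rat 2. Both mPES rats lay above both ischemia rats for Hbb in neurons (4.19 and 5.26 against 9.67 and 14.6) and for Hba-a1 in OPCs (4.93 and 3.64 against 27.9 and 36.9) and microglia (14.7 and 13.6 against 60.9 and 54.6).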

How the results depend on the processing

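The neuron fits on shared sub-clusters and the OPC fits without the cycling cluster and over OPC-marker nuclei of any cluster were tests chosen only after the result was seen; the other alternatives were planned. With 2 rats per group, counts of changed genes moved more with the rat left out than with any normalization: RLE size factors gave 86 genes in OPCs and 1 in microglia, and all deposited barcodes and the neuron fits on shared sub-clusters gave 0. Leiden resolution 2 left the OPC and microglia classes with the same nuclei. Its 87 genes in OPCs and 1 in microglia therefore repeat the main fit and do not test it.

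DESeq2 called 15 genes over all nuclei, 22 in neurons, 21 in OPCs, 2 in astrocytes, 15 in inhibitory neurons and 3 in oligodendrocytes, and limma on equally weighted nuclei 14 in OPCs. With no filter on low counts the counts were 190 in OPCs, 96 in astrocytes, 59 in cholinergic neurons, 77 in endothelial cells, 1 in inhibitory neurons, 38 in microglia, 46 in monoaminergic neurons, 7 in mural cells, 24 in newly formed oligodendrocytes, 246 in oligodendrocytes and 1 for excitatory against inhibitory neurons. With doublets kept, and without the cycling cluster, 1 gene passed in OPCs, and over OPC-marker nuclei of any cluster 5 did; 72 of the 75 nuclei of that cluster lay in an unnamed cluster when doublets were kept. With an estimated correlation 0 lists passed, and with fry 0. Otherwise the cause was not tested.

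With each rat left out in turn the counts ranged from 39 to 205 in OPCs, 0 to 382 in astrocytes, 0 to 263 in cholinergic, 0 to 145 in inhibitory and 0 to 287 in monoaminergic neurons, 0 to 147 in neurons, 0 to 136 in endothelial cells, 2 to 195 in microglia, 3 to 28 in mural cells, 13 to 123 in newly formed oligodendrocytes, 0 to 299 in oligodendrocytes, 0 to 11 over all nuclei, 0 to 1 for the interaction, 43 to 109 for lists and 0 to 1 for shares of nuclei. Each such fit rests on 3 rats, and beyond that the cause was not tested.

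Replicate numbers were not shown to pair the rats: with 2 pairs, deviations of rats of the same number correlated between -0.00224 in OPCs and 0.33 in excitatory neurons. Grouping the rats by replicate number in place of treatment called 17 genes in excitatory neurons, 16 in astrocytes, 9 in mural cells, 8 in oligodendrocytes, 6 in neurons and 5 in microglia, against 0 for the real groups (1 in microglia), and 0 in OPCs, which points to a structure of the samples that follows the number. With the replicate block the counts were 158 in OPCs, 5 in astrocytes, 4 in endothelial cells (Nr4a1, Btg2, Hbb and Hba-a1), 21 in inhibitory neurons, 12 in microglia and 3 in mural cells (Col18a1, Hs3st4 and Zbtb16), 0 in the other fits, and 88 for lists.

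Some directions reversed, and the cause was not tested. With doublets kept Kcnq5 in endothelial cells had a log2 fold change of -0.2922 and Rreb1 in inhibitory neurons of -0.04683 (-0.05132 at Leiden resolution 2), and in endothelial cells the lists of glutamate receptors and voltage-gated channels had adjusted p of 0.9132 and 0.8975. With each rat left out, the lowest and highest adjusted p of lists that reversed were as follows, the highest without mPES rat 2 for the next 3 lists. Ribosomal proteins had 1.972e-30 to 0.5154 over all nuclei, 1.294e-24 to 0.3882 in oligodendrocytes, 2.675e-09 to 0.7213 in neurons and 2.061e-07 to 0.7287 in inhibitory neurons. Mitochondrially encoded genes had 2.095e-31 to 0.8496 in oligodendrocytes, 4.79e-11 to 0.6732 in monoaminergic neurons and 2.106e-12 to 0.6159 in newly formed oligodendrocytes, and monoamine and neuropeptide transmission 3.328e-06 to 0.9835 over all nuclei. Without ischemia rat 1 the glucocorticoid response reversed in oligodendrocytes (1.54e-67 to 0.1417), astrocytes (5.198e-26 to 0.6233) and all nuclei (0.1374, with 1.442e-39 to 0.1487 over the 4 fits), as did HOX genes in inhibitory neurons (0.4698, with 2.386e-19 to 0.7287 over the 4 fits) and astrocytes (4.427e-12 to 0.9487).

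Of the named genes, 108 kept direction and side of the threshold with RLE size factors and 1 lost its call; with DESeq2 88 kept both, 15 gained a call and 6 lost it. Of the 82 lists called, 81 stayed called with RLE size factors and 70 with doublets kept. The share of simulated 2-fold changes that edgeR called did not follow the depth of a class, with 21% in endothelial cells, 24% in microglia, 38% in excitatory neurons, 40% in mural cells and 74% in inhibitory neurons. Changed genes were drawn above a minimum mean count, so these shares leave out the genes of low count in each class.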

Other observations

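The tests of dividing cells of other classes, of macrophage markers, of placement as a part of the folds and of the share of oligodendrocytes were chosen only after the result was seen. In cholinergic neurons, 2 lists of cell stress were lower in the mPES rats. Of the hypoxia response genes 12 of 12 were lower, with a median log2 fold change of -0.22 (camera, adjusted p = 0.0476; adjusted p = 0.945 with an estimated correlation), among them the oxygen sensor Egln1 (-0.54, SE 0.26) and Vegfa, which drives vessel growth (-0.55, SE 0.35). Of the heat shock and unfolded protein genes 16 of 19 were lower (adjusted p = 0.0377; 0.945 with an estimated correlation), with Xbp1 at 18.3 and 16.1 CPM against 6.29 and 3.16 and Atf4 at 20.4 and 14.9 against 7.08 and 10.5. Leaving out any 1 rat ended both calls, with adjusted p of 0.281, 0.418, 0.270 and 0.247 for the hypoxia list and 0.179, 0.318, 0.178 and 0.0678 for the heat shock list without ischemia rats 1 and 2 and mPES rats 1 and 2. The class held different sub-clusters in ischemia rat 1: one led by Col5a2 and Pappa2 held 59.5% of its cholinergic neurons and 8.64%, 5% and 10.2% of those of ischemia rat 2 and the mPES rats, and one led by Cadps2 and Nckap5 held 0 of 37 against 17.3%, 17% and 16.3%. In endothelial cells 15 of 16 genes of TGF-beta signalling were lower (median -0.47, adjusted p = 0.000953; 0.945 with an estimated correlation), with Bmpr2 at 671 and 518 against 359 and 357 CPM; without ischemia rat 1 the adjusted p was 0.115. Phagocytosis genes were higher in neurons, 14 of 16 with a median of 0.18 (adjusted p = 0.001; 0.945 with an estimated correlation), among them Megf11 (0.42, SE 0.11) and the integrin Itgav (0.51, SE 0.16); without ischemia rat 1 the adjusted p was 0.0932 and without mPES rat 2 it was 0.0501. Nuclear-encoded genes of oxidative phosphorylation were higher in astrocytes, 39 of 49 with a median of 0.23 (adjusted p = 7.06e-05; 0.945 with an estimated correlation), with an adjusted p of 0.729 without mPES rat 2. In microglia synaptic vesicle genes, which neurons express, were higher in 15 of 20 cases (median 0.46, adjusted p = 0.000485; 0.945 with an estimated correlation), with an adjusted p of 0.0660 without ischemia rat 1 and 0.200 without mPES rat 2. Reactive astrocyte genes passed in no class (lowest adjusted p 0.0895).

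Dividing nuclei of the microglia class were seen in ischemia rat 1. After thinning to 1000 UMIs, 27 of its 180 nuclei of the class (15.0%, exact 95% interval 10.1 to 21.1%) held at least 2 cell cycle UMIs, against 2 of 153 in ischemia rat 2, 1 of 64 in mPES rat 1 and 0 of 54 in mPES rat 2 (which allows up to 6.60%); 52, 105, 91 and 70 nuclei had too few UMIs, and the shares without thinning were 16%, 1.55%, 1.29% and 1.61%. That rat's microglia lay almost wholly in a cluster of their own (96.1%), in which the macrophage gene Mrc1 stood at 492 CPM (in 38 of 255 nuclei) and the microglia gene P2ry12 at 720, against 1.84 and 357 in the other microglia cluster, so the class holds some nuclei with macrophage markers. A UMI of a macrophage marker was found in 2 of the 27 dividing nuclei (7.41%, exact 95% interval 0.910 to 24.3%) and in 39 of the 153 others (25.5%, 18.8 to 33.2%), and a microglia marker in 27 and 152. It is also the rat with Fkbp5 at 521 CPM in microglia. Mblac1, which lies near the Pilrb family on its chromosome in the gene table of assembly GRCr8, was at 6.45 and 6.40 CPM over all nuclei of the ischemia rats and at 1.56 and 2.39 in the mPES rats (log2 fold change -1.70, SE 0.26, edgeR adjusted p = 0.912, DESeq2 0.00119), and Pilrb-ps6 at 7.88 and 7.46 against 0.378 and 0.0262 over all nuclei and at 0.881 and 0.755 against 0.0472 and 0 in neurons. A sequence difference between the rats at this locus was not tested and stays open for both genes.

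Mitotic transcripts in OPCs of the mPES rats may reflect more dividing precursors, as a hypothesis. Deeper nuclei are argued against, because the lower mPES rat kept 9.388% of OPC nuclei with cell cycle UMIs after thinning, with an exact interval from 6.04% that lies above the 5.07% and 5.22% at which the intervals of the ischemia rats end. Placement by the clustering is argued against as the whole cause, since among thinned nuclei with at least 5 UMIs of OPC markers, whatever their cluster and doublet score, the lower mPES rat had 4.883% (3.18 to 7.12%) and the higher ischemia rat 1.21% (up to 2.80%), but as a part of the folds in the class it stays open: of nuclei with at least 4 cell cycle and 10 OPC marker UMIs, 25% (5.49 to 57.2%) at most lay in the OPC class in an ischemia rat and at least 51.5% (33.5 to 69.2%) in an mPES rat, and over OPC-marker nuclei of any cluster 5 genes passed instead of 87. Dividing astrocytes or microglia among the OPCs are argued against, since their markers reached at most 5.961% of their own class's level in the cycling cluster, while a part from oligodendrocytes stays open, with their markers at 21.23% of that level (4063 CPM against 2183 in the larger OPC cluster) and OPC markers at 6514 CPM. Differences in lesion size or in the level of the brainstem dissected were not tested and stay open, and only 3 splits of the 4 rats exist, too few to judge chance, with 87 genes in the real one and 0 in the highest other.

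Myelin transcripts in neurons of the mPES rats could come from other cells, and the tests leave this open. A larger share of oligodendrocytes in the library cannot be told apart, because the rats are too few: mPES rat 1, with the lowest share (16.5%), had 1615 myelin CPM in neurons, mPES rat 2, with the highest (31.6%), had 1877, and the ischemia rats had 1178 and 1367. Whole oligodendrocyte nuclei in the neuron droplets cannot be told apart from a change in neurons: 238 other genes enriched in oligodendrocytes had a median log2 fold change of 0.254 in neurons (bootstrap interval 0.189 to 0.288), near 50% of the 0.57 of the myelin list. Free RNA cannot be told apart either, since myelin UMIs grew with the total UMIs of a neuron with exponents up to 0.7721, between the values set for free RNA and for transcripts of the neuron itself.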
